A study of Mus musculus with 3 samples.

How the data were processed

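RNA levels were measured in 3 samples of normal mouse muscle, which form the only group in the labels used here. Per the labels' protocols, total RNA of normal muscle was extracted with Trizol, and 500 ng was amplified and labelled with biotin for hybridisation. The array is a 3' expression array on which several short probes near the 3' end of a transcript make up a probe set. The authors deposited log2 values, 1 per probe set and array, and the submitters' processing notes name RMA. RMA subtracts background, brings the distribution of probe signals on all arrays into line by quantile normalization, and summarises the probes of a probe set on the log2 scale. Its version, and which arrays were normalized together, are not given in the sources used here. Quantile normalization removes differences in overall brightness between arrays, so a change shared by most genes would not be visible in these values. The values have no detection calls and no probe-level signals, so saturation could not be tested for each probe set.

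The table held 22690 probe sets. Platform annotation from GEO gave 1 gene for 20393 of them, several genes for 691 and none for 1606, of which 64 were control probe sets. Symbols were checked against a RefSeq gene table of the mouse assembly GRCm38.p6 through the Entrez gene number, which matched for 20364 probe sets. No symbol changed. No genomic coordinates are given, because the build behind the probe annotation is not named. Probe sets assigned to several genes or to none were left out of gene values. The level of a gene was that of its probe set with the highest mean over the 3 muscles, which gave 12394 genes.

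A background level was set for each muscle as the 95th percentile of 110 probe sets of 74 genes of retina, testis, liver, brain, pancreas, gut, kidney and other organs. A gene above this level is called detected. Of the 74 background genes, 5 were themselves detected in all 3 muscles, since a gene is judged by its highest probe set or may be expressed. A list with few detected members may thus hold false calls. Probe sets differ in how strongly they bind, so the levels of different genes were not ranked against each other, and a gene below background may still be expressed. The mean and SD of each gene were taken over the 3 muscles (n = 3). The range of a gene is its highest minus its lowest muscle, and a departure is the level in a muscle minus the mean of the other 2. A departure or range of 1 on the log2 scale is a 2-fold difference.

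With a single group there is no contrast to test. Genes that vary more than others of like level were sought with limma 3.58.1 in R 4.3.3. The variance of each gene detected in at least 1 muscle, with 2 degrees of freedom, was set against limma's prior variance distribution, fitted robustly and with a trend on the mean level. A one-sided F test with Benjamini-Hochberg adjustment at 0.05 followed. The labels do not say whether the muscles came from separate animals, so every SD and p-value measures only the spread between these samples, which may be technical. For 38 gene lists the median departure in each muscle was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list of at least 5 detected members was called apart in the outermost 0.5% at either end, if its median departure was at least 0.25 in size. These percentiles describe these 3 samples and are not tests.

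The lists, the background genes, the size limits and the rule for named genes were fixed before the data were examined. Named genes are the first 4 detected members of each list in its written order, every member of the lists of myogenic regulators, sarcoma genes and sex chromosome genes, and the 30 genes with the largest range. Had a list been called apart, its 4 members departing most would have been named too. Genes named outside this rule are said to have been chosen after their values were seen.

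The methods were tested on simulated data with the real mean levels and the fitted variances of the 7837 genes, over 5 simulations. When 1 muscle was moved by 2 on the log2 scale, limma's variance test called 92.8% of the moved genes, and for a move of 1 it called 49.2%. The range rule found 100% and 67.2% of the same genes. When nothing was moved, 1 call in 39185 tests was made, and the range rule took 21.2 genes per simulation. In 1 simulated data set a shift of 0.3 of a whole list in 1 muscle was found for 31 of 34 lists, with 0 of 102 list and muscle values called when nothing was shifted.

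The alternatives were quantile normalization or median centring of the 3 columns, the mean over a gene's probe sets, leaving out probe sets marked as matching several transcripts, a background level at the 99th percentile, no background filter, leaving out each muscle, a 1.5-fold limit on the range, other limma settings, and 2 other rules for lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for all other steps.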

Results

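Gene expression was profiled by microarray in 3 samples of normal mouse muscle, named muscle 1, muscle 2 and muscle 3. They were taken from littermate controls aged 3 to 6 weeks, with 1 array per muscle. In the study these samples were the normal reference for tumours derived from satellite cells, the Pax7-expressing stem cells that lie along muscle fibres. The study asked how tumours from cells transformed in vitro and tumours arising in vivo relate to each other, to another mouse sarcoma and to human sarcomas of soft tissue. Tumour arrays were not analysed here, so the values below describe the reference tissue and the error on it, and no tumour was compared with normal muscle. All levels are log2 RMA values, given as mean ± SD over the 3 muscles (n = 3). The median over all probe sets was 6.12 in each muscle, and the number of arrays limits the precision. The background level was 5.87 in muscle 1, 5.86 in muscle 2 and 6.04 in muscle 3. Above it lay 7213 of 12394 genes in all 3 muscles, and 4557 genes were below it in every muscle.

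The contractile programme of mature muscle was detected throughout. All 14 measured genes of the fast fibre list were above background in every muscle. Among them the fast myosin heavy chains Myh4, Myh1 and Myh2 were at 13.26 ± 0.03, 13.37 ± 0.03 and 12.99 ± 0.02, and the fast troponin Tnnt3 was at 13.38 ± 0.02. All 11 slow fibre genes were detected as well. The slow myosin heavy chain Myh7 was at 11.24 ± 0.06, and the slow troponins Tnnt1, Tnni1 and Tnnc1 were at 10.74 ± 0.02, 10.18 ± 0.02 and 11.33 ± 0.06. Each of the 17 shared genes of the sarcomere and of excitation-contraction coupling was detected, with the actin Acta1 at 13.62 ± 0.03, titin (Ttn) at 13.25 ± 0.03, the creatine kinase Ckm at 13.61 ± 0.01 and the Z-disc actinin Actn2 at 11.38 ± 0.04. No member of these 3 lists had a range above 0.189 between muscles. Several of these probe sets lay close to the highest value on any array, 13.7, and saturation could not be tested.

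Genes typical of developing muscle were detected in part. Their list held contractile genes, but also acetylcholine receptor subunits, an adhesion gene and the growth factor Igf2. Of 12 measured genes, 8 were above background in all 3 muscles and 3 in none. The embryonic myosin Myh3 was at 6.95 ± 0.09 and the perinatal myosin Myh8 at 6.49 ± 0.12. Cardiac actin (Actc1) was at 13.43 ± 0.02 and the embryonic light chain Myl4 at 7.32 ± 0.05. Of 11 genes of the neuromuscular junction, 7 were detected in every muscle. Some genes, Chrna1 among them, were in both lists. The acetylcholine receptor subunits Chrne, Chrna1 and Chrnb1 were at 6.66 ± 0.05, 8.45 ± 0.04 and 8.98 ± 0.04, and rapsyn (Rapsn), which clusters the receptors, was at 7.42 ± 0.08.

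The gene that defines the cell of origin in this study, Pax7, was below background in all 3 muscles, at 5.31 ± 0.19. Of the 20 measured satellite cell and myogenic regulators, 14 were detected in every muscle and 6 in none. Over all 12394 genes these counts were 7213 and 4557. The myogenic factors Myf5, Myod1, Myog and Myf6 were at 6.56 ± 0.13, 7.72 ± 0.09, 8.59 ± 0.11 and 9.70 ± 0.09. Mef2c and Mef2a, which act with these factors in differentiated muscle, were at 11.13 ± 0.04 and 9.95 ± 0.03. The satellite cell surface genes Cdh15, Itga7, Sdc4 and Vcam1 were above background, at 7.31 ± 0.11, 8.26 ± 0.02, 8.98 ± 0.07 and 7.06 ± 0.14. Pax3, Eya1, Calcr, Chrdl2 and Met were the other members below background, with means from 4.12 for Met to 4.96 for Eya1. The widest range among detected members was that of the homeobox gene Six4, 0.522, with a mean of 7.79 ± 0.26. These levels are those of the highest probe set. Among detected members, other probe sets were below background in every muscle for Six4, 4.12, Mef2a, 4.64, Sdc3, 5.64, and Vcam1, 5.13 and 5.56. Satellite cells are a small share of the nuclei of muscle, so a level below background in whole tissue does not show that the gene was silent in them.

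Genes tied to sarcoma were in part above background in normal muscle. Of 19 measured, 13 were detected in all 3 muscles, 5 in none, and Igf1r in 2. Over all genes 7213 of 12394 were detected in all 3 muscles, so the count says little about this list. The retinoblastoma gene Rb1 was at 8.83 ± 0.03, the p53 antagonist Mdm2 at 8.43 ± 0.04 and the cell cycle kinase Cdk4 at 8.04 ± 0.06. The hedgehog receptor Ptch1 was at 7.99 ± 0.11 and Gli2 at 6.46 ± 0.17, while Gli1, a transcriptional target of the same pathway, was below background at 4.65 ± 0.31. The growth factor Igf2 was at 11.55 ± 0.01 and Myc at 7.15 ± 0.13. These levels are those of the highest probe set of each gene. Another probe set was below background in every muscle for Igf2, with a mean of 4.62, Ptch1, 5.65, Gli2, 5.56, and Mdm2, 5.67. The same held for members counted above without a level: Nf1, 3.55, Fgfr1, 5.31, Pdgfra, 3.64, Igf1r, 5.07, and Mycn, 4.17 and 3.96. All probe sets of Cdk4 were above background. Cdkn2a, Fgfr4 and Hmga2 were below background in every muscle, at 3.32 ± 0.40, 5.13 ± 0.39 and 4.74 ± 0.13. No detected member had a range of 1 or more. Proliferation genes were split, with 10 of 24 detected in all 3 muscles and 11 in none. Mki67 and Top2a, both expressed in dividing cells, were at 7.43 ± 0.18 and 6.80 ± 0.13. Of 16 targets of p53, 14 were detected in every muscle, with the cell cycle inhibitor Cdkn1a at 8.51 ± 0.06 and Ccng1 at 12.50 ± 0.04.

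**Figure D1:**
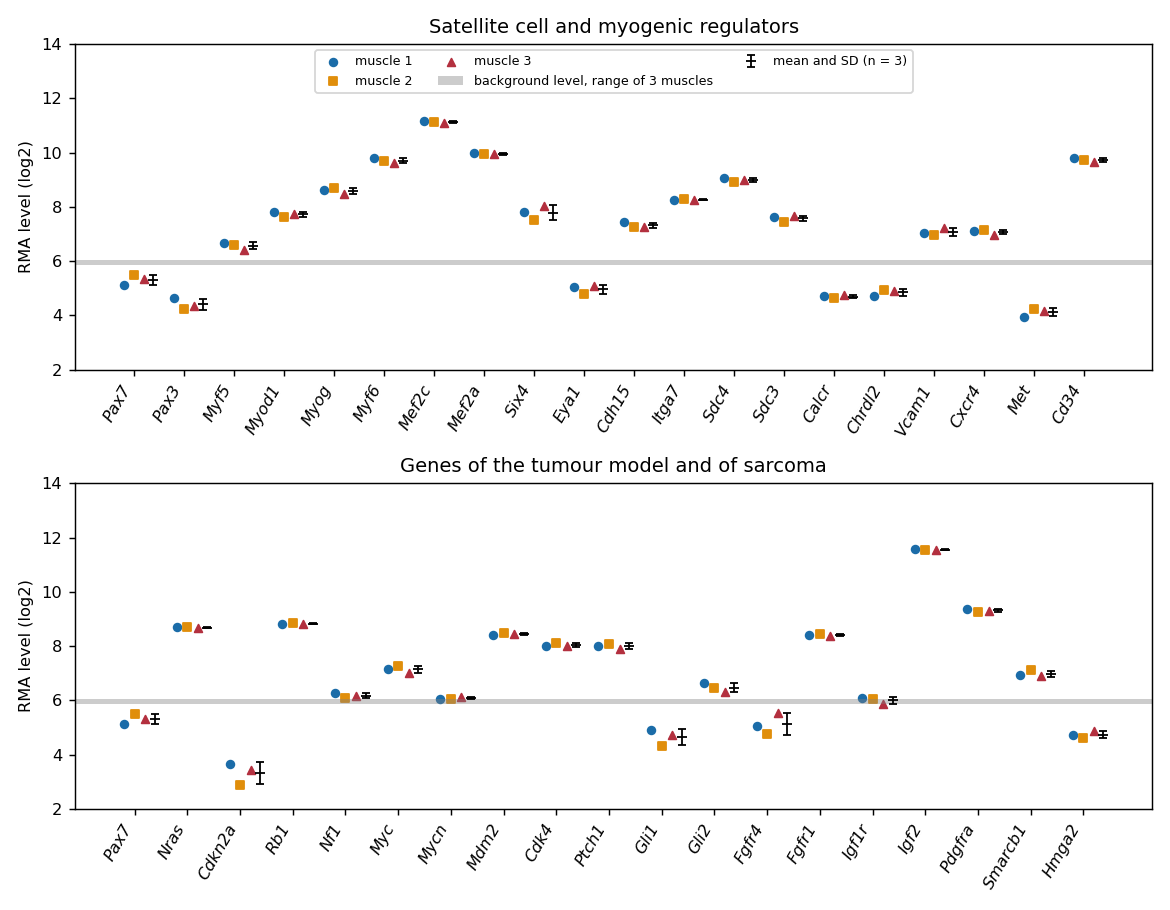
Log2 RMA level (y axis) of each measured gene (x axis) of the myogenic regulator list (top) and the sarcoma list (bottom) in the 3 muscles (coloured points), with the mean and SD in black and the background level as a grey band. Pax7, at 5.31 ± 0.19, lies below the band in all 3 muscles, and Myf5, Myod1, Myog and Myf6 lie above it.

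The lists of markers for other cell types of muscle tissue had similar levels in the 3 samples. Some members were shared between lists, such as Fabp4 by the adipocyte and endothelial lists. Others were also in the sarcomere or fatty acid lists. The counts alone therefore do not show that each cell type was present. Of 22 fibroblast and matrix genes, 21 were detected in every muscle, with the collagens Col1a1, Col1a2 and Col3a1 at 11.36 ± 0.07, 12.88 ± 0.04 and 13.10 ± 0.02. For tendon the count was 9 of 12, with the tenomodulin gene Tnmd at 7.21 ± 0.04. In the endothelial list 15 of 17 genes were detected in all muscles, with Pecam1 at 6.49 ± 0.10 and Cdh5 at 8.49 ± 0.17, and in the smooth muscle and pericyte list 12 of 13, with Acta2 at 11.24 ± 0.02. Adipocyte genes were detected in 15 of 18 cases. The adipocyte hormone Adipoq was at 10.51 ± 0.10 and the lipid carrier Fabp4 at 12.23 ± 0.02, whereas the hormone leptin (Lep) ranged from 5.36 in muscle 3, below background, to 6.60 in muscle 2. Macrophage genes were detected in 15 of 20 cases, with Adgre1 and Csf1r at 8.44 ± 0.15 and 9.80 ± 0.09. Other blood cell lists were detected less completely: 8 of 15 lymphocyte genes, 4 of 10 genes of antigen presentation, 5 of 9 mast cell genes and 2 of 12 neutrophil genes. For the background genes the count was 5 of 74, which is low by construction, since their own probe sets set the background level. Over all genes it was 7213 of 12394. Cd3e, a subunit of the T cell receptor complex, was at 7.33 ± 0.19, and the antigen-presenting gene H2-Aa at 9.70 ± 0.05. Of 11 erythroid genes 2 were detected, but the main globin probe sets carry several gene names and were left out of gene values. Those 4 globin probe sets had means from 9.75 to 12.96 and a largest range of 0.145.

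Energy metabolism genes were detected almost without exception. All 24 genes of oxidative phosphorylation were above background in each muscle, with Ndufa4 at 12.80 ± 0.01. The same held for 20 of 21 genes of glycolysis and glycogen, with Pfkm at 12.30 ± 0.02 and Aldoa at 13.56 ± 0.02, for 21 of 22 genes of mitochondria and fatty acid use, and for all 20 ribosomal protein genes. The mitochondrial regulator Ppargc1a was at 8.10 ± 0.17. Genes that respond to handling, time of day or hormones were also detected. In the immediate early list 17 of 21 were, with Fos at 8.13 ± 0.11 and Jun at 9.50 ± 0.01. In the clock list 12 of 16 were, with Clock, Per1 and Per3 at 7.21 ± 0.07, 8.76 ± 0.03 and 8.08 ± 0.13. All 17 glucocorticoid responsive genes and all 18 measured genes of atrophy and autophagy were detected, with Fkbp5 at 6.48 ± 0.08, Tsc22d3 at 10.85 ± 0.04 and the ubiquitin ligase Fbxo32 at 7.28 ± 0.42. Of 17 heat shock genes 16 were detected, and of 19 interferon responsive genes 10, against 7213 of 12394 over all genes. In the growth axis list 16 of 17 were, with Igf1 at 10.53 ± 0.07.

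The 3 muscles differed little from each other. Over genes detected in all of them the median SD was 0.0781, a factor of 1.06, and 95% of these genes had an SD under 0.226. Across 7837 genes, which are not independent replicates, Pearson's r was 0.995 between muscles 1 and 2, 0.993 between 1 and 3 and 0.992 between 2 and 3. Spearman's rho was 0.993, 0.991 and 0.990 for the same pairs. The SD of the difference was 0.166 for muscles 1 and 2, 0.194 for 1 and 3 and 0.201 for 2 and 3. Spread depended on level: the median SD was 0.149 in the 1568 genes with the lowest means and 0.0417 in the 1568 with the highest.

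**Figure D2:**
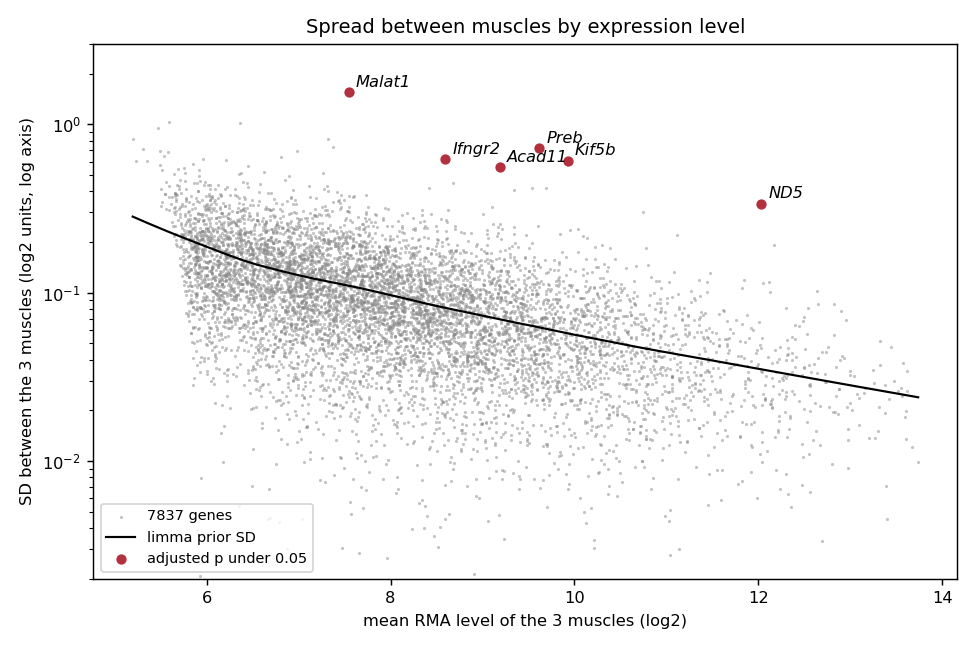
SD between the 3 muscles in log2 units (y axis, log scale) against the mean log2 RMA level (x axis) for 7837 genes detected in at least 1 muscle (grey), with limma's prior SD as a line and the 6 genes of excess variance in red. The median SD falls from 0.149 in the 1568 genes with the lowest means to 0.0417 in the 1568 with the highest.

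A range of at least 2-fold between muscles was found for 28 genes, 22 of them with a mean under 7 and only 9 above background in all 3 muscles. Simulated data without any change gave 21.2 such genes on average. The simulated variances were fitted to the spread of these 3 muscles, so any real difference between them is part of that count. It therefore does not tell how many of the 28 arose by chance. Muscle 3 was the muscle farther from the others in most, lying above them in 17 of the 28 and below them in 5. The nuclear non-coding RNA Malat1 had the widest range, at 6.74 in muscle 1, 6.56 in muscle 2 and 9.33 in muscle 3, a 6.79-fold span. The transcription factor gene Zbtb7a, the chromatin remodeller Atrx, Wdfy3, Pcp4l1 and the DNA demethylation enzyme Tet1 were each highest in muscle 3. Pcp4l1 spanned 2.80-fold and was above background throughout, whereas the other 4 were above background in muscle 3 only, at 6.69 for Zbtb7a, 6.53 for Atrx, 7.53 for Wdfy3 and 6.15 for Tet1, so their folds are not given. The potassium channel gene Kcnj12 was at 8.22 in muscle 3, against 6.87 and 7.04 in muscles 1 and 2. Preb was lowest in muscle 3, at 8.78 against 10.01 and 10.06. Leptin, Omd and Galnt3 were among the few that stood apart elsewhere, the first 2 highest in muscle 2 and Galnt3 highest in muscle 1, each with at least 1 muscle below background. Without muscle 3 the count was 2 genes, without muscle 2 it was 18, with a stricter background level 11 and with probe sets averaged 16.

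**Figure D3:**
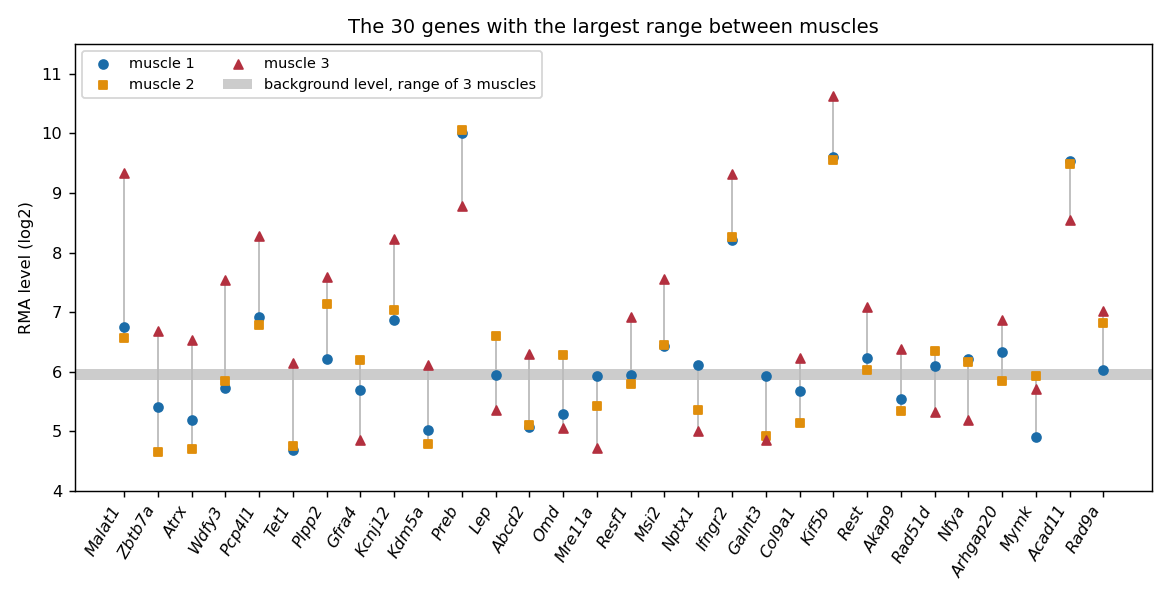
Log2 RMA level (y axis) in each muscle (coloured points) of the 30 genes with the largest range between the 3 muscles (x axis, widest on the left), with the background level as a grey band. Malat1 spans 6.56 to 9.33, and in most genes the point of muscle 3 lies apart from the other 2.

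Tested against the variance of genes of like level, 6 of 7837 genes varied in excess. At an unadjusted p under 0.05 there were 401 genes, where chance would give 392. The prior was fitted to these same genes, which by itself brings the 2 counts close. Their closeness therefore does not show that the muscles differ only by chance. By limma's variance test the adjusted p was 0.0028 for Malat1, 0.0055 for Preb, 0.0072 for the kinesin Kif5b, 0.0107 for the mitochondrially encoded ND5, 0.0314 for Acad11 and 0.0361 for the interferon gamma receptor subunit Ifngr2. ND5, which falls outside the rule for named genes, was named after its values were seen. In all 6 the muscle apart was muscle 3, by 2.67 for Malat1, 1.05 for Kif5b, 0.58 for ND5 and 1.08 for Ifngr2, and by -1.25 for Preb and -0.96 for Acad11. Other probe sets of the same gene did not follow in every case. For Kif5b the remaining 4 probe sets departed by between -0.16 and 0.37 in muscle 3, for Preb the other departed by -0.03 for Ifngr2 by 0.25 and for Acad11 by -0.27, and for Malat1 the other 3 detected ones departed by 2.37, 1.04 and 0.42. By limma the count was 13, with all 6 among them, after quantile normalization, and 0 when the probe sets of a gene were averaged or no trend on level was fitted, with 308 and 259 genes at an unadjusted p under 0.05, and without probe sets matching several transcripts Malat1 and Preb were not among the genes called. Leaving out muscle 3 left 1 gene, Atp5j, that was not among the 6 and was named after its values were seen, and leaving out muscle 1 left Malat1 alone.

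No gene list stood apart in any muscle. Over 34 lists with 5 or more detected members, 0 of 102 list and muscle values met the rule, and none lay in the outermost 0.5% at either end whatever its size. In the outer 5% lay 6 values, where chance would place 5.1. The largest median departure was that of the lymphocyte genes in muscle 1, 0.20, with 7 of 9 members higher there than in the mean of the others. Macrophage genes were next among the 6, with a median departure of 0.09 in muscle 2 and 11 of 15 members higher. The remaining 4 values, for adipocyte, glycolysis and ribosomal protein genes, were at most 0.03 in size. In simulated data a shift of 0.3 was found for 31 of 34 lists, so shifts of that size shared by a whole list would mostly have been seen.

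Signal along control transcripts was measured as the 3' minus the 5' level. For Gapdh it was 0.377 ± 0.048, for Actb 0.709 ± 0.089, for the transferrin receptor 1.87 ± 0.10 and for pyruvate carboxylase 2.74 ± 0.08. Both transferrin receptor probe sets were below background in every muscle, and the 5' probe set of pyruvate carboxylase was below it in muscles 1 and 3, so these values say little about RNA quality. Pyruvate carboxylase and 4 bacterial RNAs of the kind added to samples as labelling controls were included after the data were seen. For dap the difference was 4.13 in muscle 1, 3.99 in muscle 2 and 3.04 in muscle 3, and for thr it was 4.09, 3.91 and 2.82. For phe and lys it varied by less, with SDs of 0.045 and 0.109. The 5' probe set of 18S ribosomal RNA was at 10.96 in muscle 1, 11.23 in muscle 2 and 11.69 in muscle 3. Muscle 3, which stood apart for most genes of wide range, also had the smallest 3' minus 5' difference in dap and thr and the highest 18S signal.

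**Figure D4:**
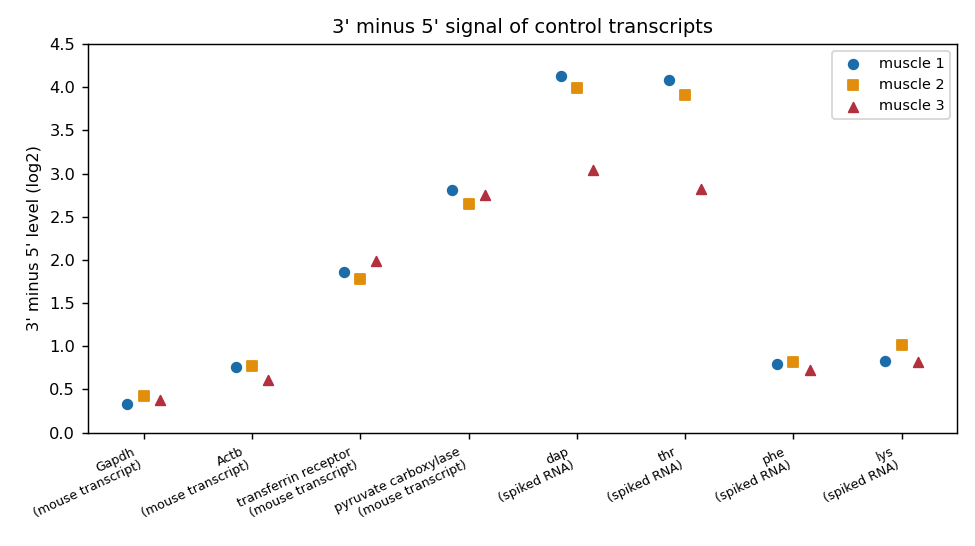
Level of the 3' minus the 5' probe set (y axis, log2) for 4 mouse control transcripts and 4 spiked bacterial RNAs (x axis) in each muscle (coloured points). For dap and thr the point of muscle 3, at 3.04 and 2.82, lies below those of the other muscles, which are at 3.91 or above.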

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

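No called result reversed, but 136 of 909 list departures under the alternatives had another sign than the main value, the largest of these being 0.47 in muscle 3 for the 2 cartilage and bone genes detected in at least 1 muscle, which became -0.08 without the filter. The count of detected genes stayed within a factor of 1.5 of its main value under every alternative run, and 0 lists were apart under each of them. The number of genes with a range of at least 1 (2-fold), 28, became 16 with probe sets averaged, 11 with the stricter background level, 48 without the filter (more genes tested) and 223 at a 1.5-fold limit, and ran from 2 to 22 when a muscle was left out, with 2 without muscle 3. The median SD of 0.0781 became 0.0681 with the stricter background and 0.103 without the filter, which drops or adds dim genes, and ran from 0.0551 to 0.0665 with 2 muscles, where the SD of 2 values has a lower median by construction. The lowest Pearson's r, 0.992, became 0.991 without probe sets matching several transcripts and 0.995 without the filter, and ran from 0.992 to 0.995 with a muscle left out. Genes of excess variance by limma, 6, numbered 13 after quantile normalization, all 6 among them. There were 0 with probe sets averaged, with 308 at an unadjusted p under 0.05, and 0 without the trend, with 259. A fit that was not robust gave 3, and leaving out a muscle gave 1 to 4. With the stricter background level and without the filter there were 4 each, and Acad11 and Ifngr2 were no longer called. For the changed counts and correlations not given a cause here, the cause was not tested. The 3' minus 5' values of Gapdh, Actb and the transferrin receptor stayed within their SD under both normalizations. Of 1809 values of the mean level of 206 named genes under the alternatives, 1698 stayed within 1 SD. Of 265 values of range for the 30 widest genes, 203 stayed on their side of 2-fold, 61 fell below it and 1 rose above it. No paired analysis was possible because the labels give a single group. The arrays give no probe-level signal over background, so the limit on dim genes is the background level alone, and a change under about 2-fold in a single gene was found by limma's test in under 50% of simulated cases.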

Other observations

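Tests of explanations in this part, for muscle 3 and for a shared source of RNA, were chosen after the results were seen. Lists not described above gave these counts of members detected in all 3 muscles, where the count over all genes was 7213 of 12394. Genes of X and Y were split: 4 of 9 were detected, with the X-inactivation RNA Xist at 10.88 ± 0.04 and the X-linked Ddx3x and Eif2s3x at 11.03 ± 0.05 and 10.82 ± 0.04. The Y-linked Eif2s3y, Kdm5d and Uty were below background in every muscle, at 3.04 ± 0.10, 3.18 ± 0.27 and 3.23 ± 0.05, and the labels used here give no sex. Skin and epithelium genes were detected in 6 of 15 cases, with the keratins Krt5 at 7.05 ± 0.16 and Krt10 at 9.24 ± 0.07. Of 11 cartilage and bone genes 1 was detected in all muscles, Col2a1 at 6.48 ± 0.14. The count was 5 for the 74 background genes, whose own probe sets set the background level. Peripheral nerve genes were detected in 5 of 10 cases, with the myelin genes Mbp at 10.04 ± 0.04 and Pmp22 at 11.31 ± 0.03. The counts were 10 of 13 for cholesterol synthesis, with Hmgcs1 at 10.13 ± 0.07, 11 of 14 for hypoxia, with Vegfa at 7.65 ± 0.19, and 5 of 5 for polyamine and androgen responsive genes, with Odc1 at 9.66 ± 0.01.

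Muscle 3 was at least 2-fold away from the mean of the others for 16 genes, 13 higher and 3 lower. The counts were 3 genes for muscle 1 and 4 for muscle 2. In 100 simulations with equal scatter on the arrays the median count was 4 and the highest 10. These simulations counted 1 fixed muscle, whereas muscle 3 was picked as the farthest. They also applied no background filter, which Abcd2, Atrx, Kdm5a, Tet1, Wdfy3 and Zbtb7a passed in muscle 3 only. The simulated variances were fitted to these same muscles. The simulations therefore give no chance level for the 16 genes. A general rise of nuclear RNA in muscle 3 was argued against by the nuclear RNAs Neat1, Meg3, Rian, Xist and Tug1, whose median departure there was -0.0080. Each was judged by its highest probe set, and a rise limited to other nuclear RNAs was not tested. A change of the whole transcript was argued against for Ifngr2, Kif5b and Preb, where another detected probe set departed by at most 0.356 of the named departure; it may hold for Malat1 and Resf1, with a ratio up to 0.885 but only 0.155 for a further probe set of Malat1, and for the other 11 genes, of which 0 had another detected probe set, it stays open, where probe sets below background departed both ways (-0.12 to 2.10 for Atrx and 0.45 for Msi2, but -0.29 for Tet1 and 0.04 and 0.41 for Nfya, opposite to the named probe sets). Labelling that reached further towards 5' ends in muscle 3, as in the dap and thr controls, cannot be told apart from other causes, since the median 5' minus 3' departure of 0.0064 rests on only 3 transcripts, of which Actb departed by 0.154, Gapdh lies near the top of the scale, where saturation could not be tested, and pyruvate carboxylase has a 5' signal below background in muscles 1 and 3, and the probe positions of the 16 genes were not used here. No biological explanation was tested, since the labels give a single group, and a difference between animals or in transcript ends stays open.

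A further hypothesis is that the 3 arrays share one source of RNA, in which case genes that often differ between animals should spread no more than others of like level. Of 6 such lists (immediate early, clock, glucocorticoid response, adipocyte, interferon response and lymphocyte), 0 had a median SD above the central 95% of 10000 random lists matched on level, and their median SDs ran from 0.0367 to 0.142, at percentiles from 2.96 for interferon response to 89.9 for immediate early genes. The lymphocyte genes had a median departure of 0.20 in muscle 1, at percentile 99.4, and the adipocyte genes 0.03 in muscle 3, at percentile 99.2. Both were picked from 102 list and muscle values, of which 6 lay in the outer 5%, where chance would place 5.1. Lep had a range of 1.24, but was picked from the widest genes and had an adjusted p of 0.72 by limma's variance test. Values picked in this way cannot count against a shared source. A shared animal or pool thus stays possible but is not shown, and littermates of like age and handling could give the same spread, which was not tested.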
